A study of Homo sapiens with 9 samples.

How the data were processed

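Transcript levels were measured on 9 Affymetrix arrays of LNCaP cells, an established androgen-sensitive human prostate cancer line. Per the labels, total RNA was extracted with Trizol and labelled with biotin through a 3′ amplification kit. The arrays fall into 3 groups of 3, named here GFP-EtOH, GFP-DHT and CCND1-DHT after the adenovirus and the treatment. Groups and replicate numbers were taken from the sample titles. The titles call the replicates biological, and nothing in the labels says that they came from separate cultures of different passages, so every p-value measures only the spread between these samples of 1 line at passage 38.

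Robust multi-array averaging (RMA) is named in the submitters' processing notes, with no version. The deposited values are linear ratios: in all 26183 rows the median of the 3 GFP-EtOH arrays was 1 within a tolerance of 1e-05, and the values ran from 0.0199 to 13.7. The authors had therefore divided each row by its GFP-EtOH median, a step read from the values and recorded in no label. The division leaves contrasts within a row as they are but removes the signal level, so it cannot be said how bright a probe set was, whether it stood above background or which of 2 genes was more abundant.

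Rows carry RefSeq transcript accessions, so the probes had been regrouped by transcript before deposition. Of the rows, 62 were array controls and 26121 had an accession, of which 20443 matched a gene symbol in the RefSeq gene table of assembly GRCh38.p14. That table was used for names only. No build is given in the sources used here, and no coordinates are printed. Transcripts of 1 gene often shared identical values, and identical rows were collapsed to 19786 distinct rows, of which 17131 had 1 gene symbol, 2625 had none and 30 had several. Rows with several symbols were left out. The log2 of each ratio was taken with no pseudocount, and a gene was represented by the mean log2 ratio of its distinct rows, which gave 15905 genes, 983 of them with more than 1 distinct row.

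The plan written before the data were examined assumed log2 intensities and represented a gene by its brightest probe set. On ratios that rule would favour rows that rise, so the mean over rows replaced it, and the planned rule became an added alternative. A planned filter on dim probe sets had no meaning without a signal level and was not run.

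Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) over all 9 arrays with group as the factor, which left 6 residual and 3.47 prior degrees of freedom. Adjustment was by Benjamini-Hochberg over genes, with a threshold of 0.05. CCND1 itself was left out of counts and lists, so that 15904 genes were counted. The comparisons were GFP-DHT minus GFP-EtOH, CCND1-DHT minus GFP-DHT and CCND1-DHT minus GFP-EtOH, with an F test over the 3 groups. Fold changes are given as log2 differences with the standard error (SE) of the fit, and group levels as mean ± SD of log2 ratios.

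For 25 gene lists written from general knowledge before the data were examined, limma's camera was run with a preset inter-gene correlation of 0.01 and adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which tests whether the members of a list move on balance one way, were run beside it. Array and list percentiles came from 10000 random lists of the same size. Most genes named in the text were fixed by a rule before the data were examined. In the closing section, MMP7 and further members of the gene families were picked after their values had been seen. The rule took, per comparison, the 10 largest changes in each direction among called genes whose groups did not overlap, up to 3 called members per list and direction, called markers of other cell types, the 5 genes called in both comparisons with the largest product of changes in opposite directions and the 5 in the same direction, and 14 genes of androgen signalling and the cell cycle whatever they did. Some genes and 1 gene list that the rule would have brought in are not reported here. Where DHT called no gene, the rule was applied to the fit with a term for 2 GFP arrays, described below, without the condition that groups do not overlap.

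Replicate numbers were checked for pairing by correlating the deviations from group means across genes. GFP-EtOH and GFP-DHT arrays of the same number deviated together, with correlations of 0.64, 0.55 and 0.39 for numbers 1, 2 and 3. Arrays of different numbers correlated about as well between 2 and 3 (0.41 for GFP-EtOH 3 with GFP-DHT 2 and 0.33 for GFP-EtOH 2 with GFP-DHT 3), so the values mostly set number 1 apart and did not tell numbers 2 and 3 from each other. This link between numbers comes from the data and from no label. Correlations of CCND1-DHT arrays with GFP arrays of the same number lay between -0.25 and 0.085, so the numbers did not pair them. Because both GFP arrays numbered 1 stood apart from the others, 2 alternatives were added after the data had been seen: a term for these 2 arrays in the fit, which left 5 residual degrees of freedom, and a fit without them. The term assumes that the CCND1-DHT arrays lack whatever set these 2 arrays apart, which no label states.

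Other settings chosen in advance were a replicate block, a fit of only the 2 groups compared, centring on the array median, a further quantile normalization, eBayes with trend and robust variance, array weights, every distinct row as a unit, a minimum of 1.5-fold, an estimated correlation in camera and leaving out each array in turn. Besides the 2 fits for the GFP arrays numbered 1, the row with the lowest accession, the row with the highest mean ratio and a replicate block with only the groups compared were added after the data had been seen.

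The tests were run first on simulated data with the spread of the 15905 measured genes. In a simulated CCND1-DHT minus GFP-DHT comparison with 200 changed genes, 72% of genes changed by 0.5 on the log2 scale and 95% of those changed by 1 were recovered, with 5 false calls among 172. A list of genes shifted by 0.2 in a simulated GFP-DHT minus GFP-EtOH comparison was found by camera, and 0 of the other lists were. The genes were simulated independently of each other. The simulation therefore cannot show how often camera with the preset correlation calls lists whose genes vary together. Arrays were simulated independently too, with 1 spread per gene, unlike the GFP arrays numbered 1, which deviated together. The shares recovered and the false calls may thus differ in the real arrays.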

Results

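Androgen drives both the secretory programme and the growth of LNCaP cells, and cyclin D1, the product of CCND1, is a cell cycle regulator. The study asked how added cyclin D1 altered the transcript response to androgen. Cells were held for 72 h in 5% charcoal-dextran-treated serum, which removes steroids and arrests growth, and were then transduced with an adenovirus carrying GFP or cyclin D1. They received 0.1% ethanol or 1 nM dihydrotestosterone (DHT), the potent natural androgen, for 18 h. There were 3 arrays each of GFP-EtOH, GFP-DHT and CCND1-DHT. Cyclin D1 cells without hormone were not analysed here, so an interaction of virus and hormone could not be tested. All values are log2 of the deposited ratio to the median GFP-EtOH array, and 15905 genes were tested.

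The arrays labelled CCND1-DHT (scores 23.2 to 25.4) stood apart from all GFP arrays on the first principal component, which held 60.7% of the variance. The 2 GFP arrays numbered 1 lay furthest from them on it, at -31.4 in GFP-EtOH and -19.6 in GFP-DHT, with the other 4 GFP arrays at -7.24 to -3.01. The second component, with 16.5%, set the 2 GFP arrays numbered 1 (scores 10.7 and 15.4) against the other 4 GFP arrays (-13.2 to -8.37). The CCND1-DHT arrays lay between them, at 4.32 to 6.71. In these 2 arrays the median of the 40 measured interferon response genes was -0.50 in GFP-EtOH and -0.47 in GFP-DHT, against -0.092 to 0.042 in the other 7 arrays. The median of the G2/M and mitosis list was also low there, at -0.43 and -0.17. The SD of their deviations from the group mean over genes was 0.193 and 0.168, while no other array exceeded 0.116.

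The gene carried by the virus did not rise in its own arrays. The 1 row that represents CCND1 (NCBI gene 595) had ratios of 1, 1.14 and 0.96 in GFP-EtOH, 1.12, 1.03 and 1.09 in GFP-DHT and 0.92, 0.88 and 0.77 in the arrays labelled CCND1-DHT. The difference from GFP-DHT was -0.33 ± 0.09 (SE, limma, adjusted p = 0.0446), in the direction opposite to the label. The adjusted p rose to between 0.0531 and 0.171 without any 1 of 7 arrays in turn, the exceptions being GFP-EtOH 1 and 2. Whether the row's probes lie within the virus insert is not given in the sources used here, so the row is no proof for or against the label, and every direction for cyclin D1 rests on the label.

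DHT in GFP-transduced cells was compared with ethanol to measure the androgen response alone. Transcripts of the secreted prostate proteases stood highest: KLK3, which encodes prostate-specific antigen, averaged 1.23 ± 0.57 (SD, n = 3) in GFP-DHT and 0.058 ± 0.11 in GFP-EtOH, and KLK2 averaged 1.3 ± 0.53 and -0.07 ± 0.13. The 74 measured androgen-induced genes had a median difference of 0.32, with 68 positive, and the 65 measured G1/S and E2F target genes had a median of 0.36, with 62 positive. No single gene passed the threshold, however. limma called 0 genes, with 1169 at an unadjusted p under 0.05 (709 higher and 460 lower) and a smallest adjusted p of 0.129. All 3 arrays of one group lay beyond all 3 of the other for 1251 genes upward and 731 downward, 12.5% of genes against 10% by chance for exchangeable arrays, which the GFP arrays numbered 1 were not.

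The same-numbered pairs differed in the same direction but by different amounts. KLK3 was higher by 1.7, 0.97 and 0.86 in pairs 1, 2 and 3, KLK2 by 2.12, 1.07 and 0.91, TMPRSS2, a transmembrane serine protease, by 1.32, 0.53 and 0.39, and FKBP5, a co-chaperone, by 1.48, 0.47 and 0.26. The replicate block left the count at 0, and a block with only the 2 GFP groups, added after seeing the data, gave 1 gene, ST6GALNAC1, a sialyltransferase (1.04, adjusted p = 0.038). Without GFP-DHT 1, 4 genes changed by DHT in GFP cells were called, among them KLK2 and TRPM8 (adjusted p = 0.012 each) and KLK3 (adjusted p = 0.0298). A term for the 2 GFP arrays numbered 1, also chosen after seeing the data, gave 83 genes, 54 higher and 29 lower, and leaving both out gave 5, all higher.

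Under that term, the largest increases were those of KLK2 (1.37 ± 0.18, SE, adjusted p = 0.0217), KLK3 (1.18 ± 0.13, adjusted p = 0.019), DTL, the substrate receptor of a ubiquitin ligase active in S phase (1.11), and TRPM8, a cation channel (1.11). ABCC4, a transporter, ST6GALNAC1, ELOVL7, a fatty acid elongase, MCM10, a replication factor, SNAI2 and KLK4 followed at 1.05 to 0.82. The largest decreases were those of SI, sucrase-isomaltase (-0.78 ± 0.11), MYLK, myosin light chain kinase (-0.77), GRAMD1C (-0.64), COL5A2 (-0.58) and HACL1 (-0.51). SNAP91, SERPINI1, ABCG2, ASAP2 and BAZ2B fell by 0.50 to 0.45. TMPRSS2 (0.75, adjusted p = 0.0538), FKBP5 (0.74, adjusted p = 0.0947), PCNA (0.36) and MCM2 (0.44) did not pass there.

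**Figure D1:**
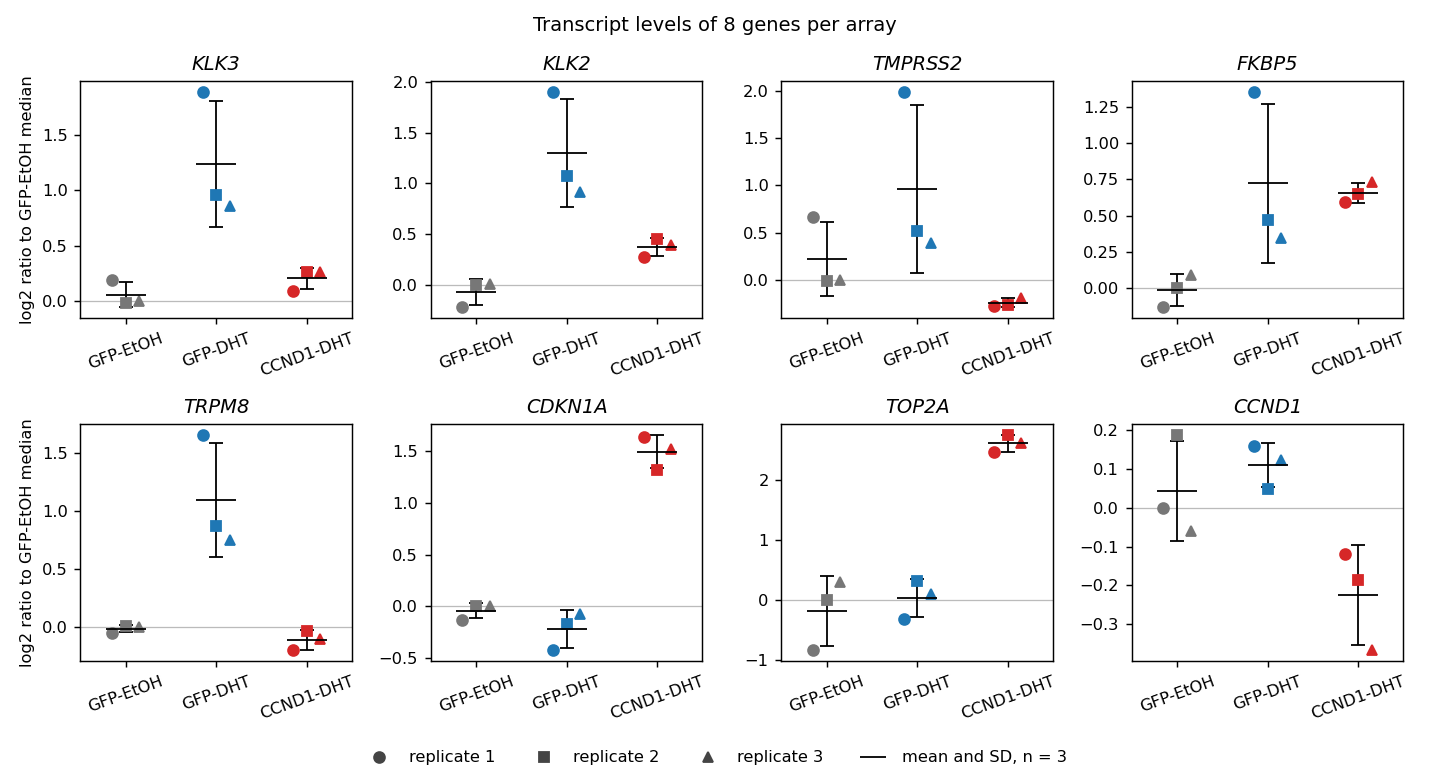
Log2 ratio to the GFP-EtOH median (vertical axis) of 8 genes in each array, by group (horizontal axis); symbols mark the replicate number, and bars give the mean and SD of 3 arrays. KLK3 and KLK2 sit highest in all 3 GFP-DHT arrays, with the array numbered 1 above the other 2, while CCND1 is lowest and CDKN1A and TOP2A highest in the arrays labelled CCND1-DHT.

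Among the lists, none had a member past the threshold over all genes in the planned fit. Adjusted over the list alone, 30 androgen-induced genes and 42 G1/S and E2F target genes passed, all higher. camera called the androgen-induced list (adjusted p = 2.26e-27) and the G1/S list (5.44e-33) higher, each with adjusted p = 0.22 with an estimated correlation, and fry gave adjusted p = 0.0536 for both. The median within pairs 1, 2 and 3 was 0.60, 0.24 and 0.17 for the androgen-induced genes and 0.61, 0.32 and 0.13 for the G1/S genes. With the added term, 17 androgen-induced genes passed, and 9 G1/S genes, among them MCM10 (0.91), MCM4 (0.69), a replicative helicase subunit, and PRIM2 (0.69), a DNA primase subunit. Without the GFP arrays numbered 1, limma called 5 androgen-induced and 0 G1/S genes. The 5′ to 3′ log2 ratio of the ACTB control probes, a sign of RNA and label length, averaged higher in GFP-DHT. It was 0.30 ± 0.16 (SD, n = 3) there and 0.055 ± 0.067 in GFP-EtOH (exact permutation test, p = 0.2). The groups overlapped, with 0.129 in GFP-EtOH 1 and 0.117 in GFP-DHT 3. The same ratio of GAPDH was 0.10 ± 0.067 in GFP-DHT and -0.00142 ± 0.0076 in GFP-EtOH (exact p = 0.1, the smallest that 3 against 3 allow).

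Genes of cholesterol and fatty acid synthesis (38 measured, median 0.23, 7 higher when adjusted over the list alone), the secretory pathway and glycosylation (43, 0.17, 10 higher), ribosome biogenesis (31, 0.14, 1 higher) and polyamine synthesis (11, 0.15, 1 higher) were called higher by camera. Their adjusted p was 5.8e-11, 1.79e-12, 6.92e-09 and 0.0218, in each case with adjusted p = 0.22 with an estimated correlation and 0.09 by fry. INSIG1 (0.45), a regulator of sterol sensing, LMAN1 (0.70), a cargo receptor between the endoplasmic reticulum and Golgi, and UAP1 (0.47), which makes a sugar donor for glycosylation, passed with the added term, and INSIG2 fell there (-0.45). The androgen-repressed list (28 measured) had a median of -0.082 (camera adjusted p = 0.0017; adjusted p = 0.22 with an estimated correlation; 0.09 by fry), with 1 gene lower when adjusted over the list alone. SERPINI1 (-0.50), a serine protease inhibitor, fell with the term. The G2/M list had a median of 0.12 (adjusted p = 0.000815; adjusted p = 0.633 with an estimated correlation; 0.6 by fry), which became -0.039 (adjusted p = 0.594) without GFP-EtOH 1 and 0.042 (adjusted p = 0.199) without GFP-DHT 2. Within pairs its median was 0.25, 0.13 and -0.022. Several of these medians rested largely on pair 1: within pairs 1, 2 and 3 they were 0.46, 0.14 and 0.052 for cholesterol and fatty acid synthesis, 0.35, 0.014 and 0.061 for ribosome biogenesis and 0.21, 0.058 and 0.039 for polyamine synthesis, but 0.22, 0.17 and 0.11 for the secretory pathway. Without the GFP arrays numbered 1 they were 0.085, 0.043, 0.051 and 0.14, and polyamine synthesis was no longer called (adjusted p = 0.0538). The call of the polyamine synthesis list was lost also without GFP-EtOH 2 (adjusted p = 0.0721), GFP-EtOH 3 (0.0746) or GFP-DHT 1 (0.189).

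Several lists that DHT left below the threshold passed it without 1 array, so their state was not settled. The ER stress and protein folding list had a median of 0.14 (camera adjusted p = 0.0763), and passed with the replicate block (adjusted p = 0.028) and without GFP-EtOH 2 (0.0256), GFP-EtOH 3 (0.0126) or GFP-DHT 1 (0.00157). The AP-1 and immediate early list had a median of -0.061 (adjusted p = 0.074; 0.00137 without GFP-EtOH 2, 0.0175 without GFP-EtOH 3 and 0.0246 without GFP-DHT 1). The cyclins, CDKs and inhibitors list stood at 0.069 (adjusted p = 0.0602; 0.0024 without GFP-EtOH 1 and 0.0372 without GFP-DHT 3), the oxidative phosphorylation list at -0.041 (0.0697; 0.00234 without GFP-EtOH 1 and 0.041 without GFP-DHT 3) and the p53 target list at -0.020 (0.0938; 0.0242 without GFP-DHT 3). Luminal prostate epithelial markers stood at 0.12 (0.0697; 0.0246 without GFP-DHT 1) and leukocyte and endothelial markers at 0.065 (0.074; 0.0256 without GFP-EtOH 2). The interferon response list went both ways, from -0.029 (0.47) to -0.22 without GFP-EtOH 1 (adjusted p = 4.82e-06), -0.12 without GFP-DHT 2 (0.0126), -0.11 without GFP-DHT 3 (0.0242) and 0.18 without GFP-DHT 1 (0.000936). With the term for the GFP arrays numbered 1, camera called the ER stress (adjusted p = 0.000155), AP-1 (0.0384), cyclins (0.0384) and luminal (0.0208) lists, and without these arrays the ER stress (0.00265), cyclins (0.00508), oxidative phosphorylation (0.024) and luminal (0.0173) lists. With an estimated correlation over all arrays none of these lists passed: the adjusted p was 0.632 for ER stress, oxidative phosphorylation, p53 targets and leukocyte and endothelial markers, 0.633 for AP-1, 0.333 for cyclins, 0.22 for luminal markers and 0.889 for interferon.

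Cyclin D1 under DHT was set against GFP under DHT, and cell cycle transcripts were prominent among the largest increases. All 54 measured G2/M and mitosis genes rose, with a median of 1.91, and 60 of 65 G1/S and E2F target genes rose, with a median of 1.02 (62 when adjusted over the list alone). TOP2A, the topoisomerase of dividing cells, rose by 2.58 ± 0.26 (SE, limma, adjusted p = 0.000278), CDC20, an activator of the anaphase-promoting complex, by 2.29 ± 0.07 (adjusted p = 5.91e-07), and CCNA2, cyclin A2, by 2.15 ± 0.15. Some androgen-induced transcripts went the other way, with 14 of 74 called lower and 2 higher: KLK3 fell by 1.03 ± 0.23 (adjusted p = 0.021) and KLK2 by 0.92 ± 0.21 (adjusted p = 0.0263), though without CCND1-DHT 1, 2 or 3 the adjusted p was 0.0929, 0.0667 and 0.0703 for KLK3 and 0.108, 0.0745 and 0.0888 for KLK2. Of 30 p53 target genes 14 rose and 2 fell, with CDKN1A, the p21 inhibitor of cyclin-dependent kinases, at 1.72 ± 0.11 (adjusted p = 1.77e-05). With an estimated correlation camera called none of these lists (adjusted p = 0.0674 for the 2 cell cycle lists, 0.492 for the androgen-induced and 0.0721 for the p53 list).

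In all, 1407 genes passed, 937 higher and 470 lower, of which 207 rose and 17 fell by at least 2-fold. The groups did not overlap for 2684 genes upward and 2362 downward, 31.7% of genes against 10% by chance for exchangeable arrays. Of the 119 genes in the 2 cell cycle lists, 114 were called higher, and they made up 32 of the 50 largest increases, 87 of the 207 increases of at least 2-fold and 114 of all 937. With the added term for the GFP arrays numbered 1 the count was 2294, which held all 1407 genes, and without those arrays it was 2817, which held 1393 of them. The number of genes changed by cyclin D1 under DHT was 2372 without GFP-EtOH 1, 801 without CCND1-DHT 1, 897 without CCND1-DHT 2 and 737 without CCND1-DHT 3.

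The largest increase was that of HSPA6, a stress-inducible heat shock protein gene, at 3.02 ± 0.29 (adjusted p = 0.000199). It was followed by TOP2A, KIF14 (2.52), a mitotic kinesin, DLGAP5 (2.5), HMMR (2.43), CEP55 (2.37), a protein of the final cut between daughter cells, CENPF (2.35), CDC20, NUF2 (2.29), a kinetochore subunit, and CENPE (2.26). The G1/S list held CCNA2, RRM2 (2.01), the small subunit of ribonucleotide reductase, and TYMS (1.76), thymidylate synthase. E2F1 rose by 0.81 ± 0.09, PCNA, the sliding clamp of replication, by 1.00 ± 0.08 and MCM2 by 1.18 ± 0.11. camera gave adjusted p = 1.06e-71 for the G2/M list and 9.79e-54 for the G1/S list, each with adjusted p = 0.0674 with an estimated correlation, and fry gave 0.000115 and 0.000137. Among cyclins, CDKs and inhibitors (35 measured, median 0.16), 12 rose and 2 fell (13 and 2 when adjusted over the list alone; adjusted p = 3.46e-06 by camera and 0.0674 with an estimated correlation). CDKN3 (1.92) and CCNB1 (1.89) rose, and MYC (-0.41) and RB1 (-0.32), the retinoblastoma protein, fell. CCNE1 (-0.11, adjusted p = 0.631), CCND2 (0.067), CCND3 (0.16) and CDKN1B (0.32) did not pass.

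**Figure D2:**
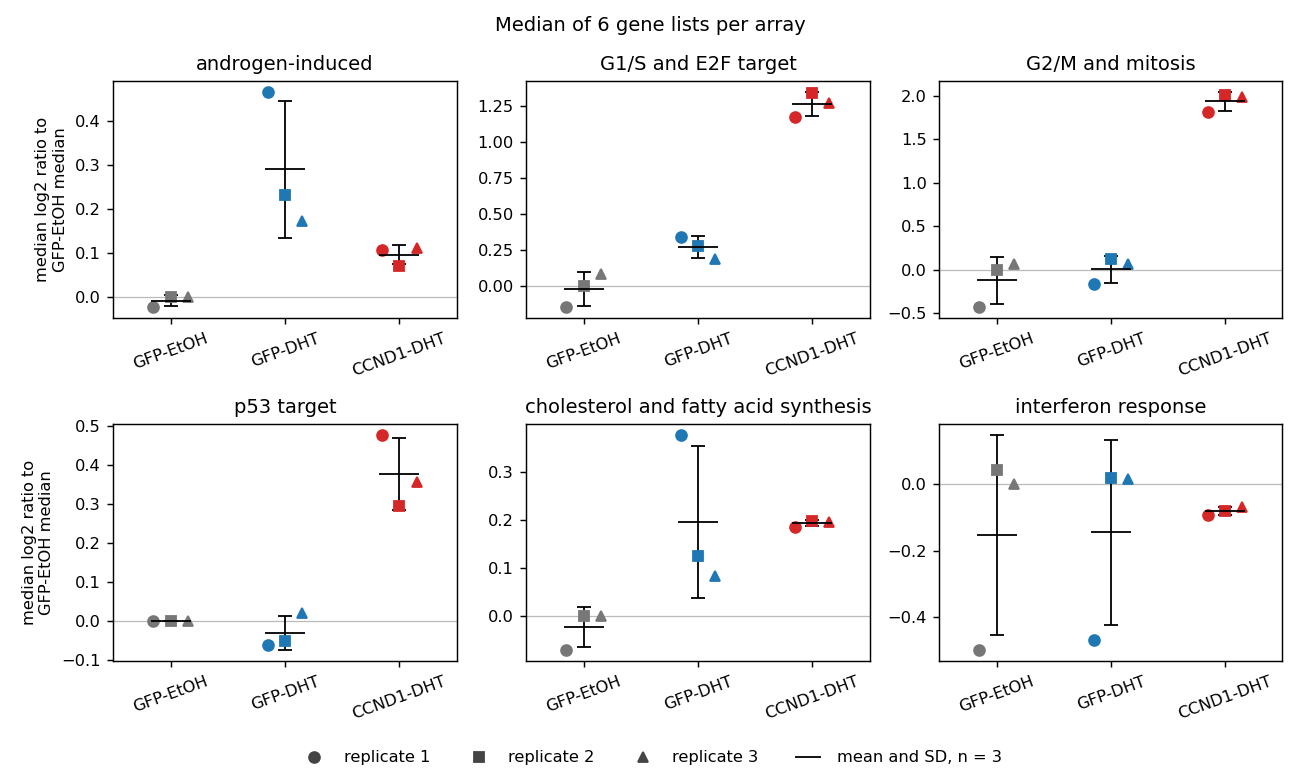
Median log2 ratio to the GFP-EtOH median (vertical axis) over the measured members of 6 gene lists in each array, by group (horizontal axis); symbols mark the replicate number, and bars give the mean and SD of 3 arrays. G1/S medians were 1.17 to 1.34 in the arrays labelled CCND1-DHT and at most 0.34 in GFP arrays, androgen-induced medians were 0.072 to 0.11 there and 0.17 to 0.47 in GFP-DHT, and the interferon medians of the GFP arrays numbered 1 were -0.50 and -0.47.

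Of the 74 androgen-induced genes, 14 fell and 2 rose in the arrays labelled CCND1-DHT relative to GFP-DHT, and 58 did not pass. Adjusted over the list alone, 22 fell and 4 rose. With the term for the GFP arrays numbered 1, 25 fell and 4 rose, and without these arrays 28 fell and 8 rose, with a median of -0.085. Over all arrays the median was -0.22 (camera adjusted p = 2.17e-06), but neither fry (adjusted p = 0.124) nor an estimated correlation (0.492) called the list. AZGP1, a secreted zinc-binding glycoprotein, fell by 1.39 ± 0.31 (adjusted p = 0.1, 0.0522 and 0.0791 without CCND1-DHT 1, 2 and 3) and TRPM8 by 1.21 ± 0.19, beside KLK3 and KLK2. NCAPD3, a condensin subunit (0.52), and FADS1, a fatty acid desaturase (0.45), rose. TMPRSS2 (-1.21 ± 0.37, adjusted p = 0.0782) did not pass, but without the GFP arrays numbered 1 it did (-0.70, adjusted p = 0.000133). FKBP5 stood at -0.067 ± 0.22, and at 0.25 (adjusted p = 0.0374) without those arrays. In the androgen-repressed list 3 genes rose and 4 fell (5 and 6 when adjusted over the list alone; median -0.019, camera adjusted p = 0.53). Without the GFP arrays numbered 1 camera called this list lower (median -0.059, adjusted p = 0.0186), with 4 genes higher and 10 lower; fry did not over all arrays (0.527). CLU, clusterin, rose by 1.20 and IGFBP3 by 0.85, while OPRK1, an opioid receptor, fell by 1.06 and ACKR3 by 0.70.

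The largest decrease of all was that of ABAT, the transaminase that breaks down GABA, at -1.79 ± 0.26 (adjusted p = 0.00253). PCDHB14 (-1.57), H2BC21, a histone gene (-1.46), RLN1 (-1.42), AZGP1, RLN2 (-1.35), BMX, a tyrosine kinase (-1.28), SOCS2, an inhibitor of cytokine signalling (-1.23), and TRPM8 were also among the 10 largest. RLN1 and RLN2 encode relaxins of very similar sequence, and PCDHB14 belongs to a family of similar genes, so their probes may share signal. In GFP-DHT 1 PCDHB14 stood at 0.83, and its change was -1.25 without the GFP arrays numbered 1.

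Of 30 p53 target genes, 14 rose and 2 fell (17 and 2 when adjusted over the list alone), with a median of 0.37. camera gave adjusted p = 5.13e-10, and adjusted p = 0.0721 with an estimated correlation. DDB2, a DNA damage binding protein, rose by 1.61 ± 0.07 and FAS, a death receptor, by 1.42 ± 0.15, while TP53INP1 (-0.69) and SESN1 (-0.63) fell. In the ER stress and protein folding list, limma called 6 of 35 higher and 0 lower (7 and 0 when adjusted over the list alone), with a median of 0.22, camera adjusted p = 0.00025 and adjusted p = 0.465 with an estimated correlation. Its median was low in the GFP arrays numbered 1 (-0.25 and -0.11), and the difference was 0.085 with the term for them (9 higher and 2 lower) and 0.12 without them (12 and 2). The 6 included TRIB3 (0.86), SESN2 (0.78) and CHAC1 (0.75), which are known targets of the amino acid and stress response rather than folding enzymes. Ribosome biogenesis genes had a median of 0.24, with 3 of 31 higher, NOP16, UTP4 and PPAN (0.28 to 0.26; 4 when adjusted over the list alone; camera adjusted p = 1.68e-05, and adjusted p = 0.483 with an estimated correlation). That count was 6 higher and 1 lower with the term, and 19 and 1 without the GFP arrays numbered 1. By fry the adjusted p was 0.000211 for p53 targets, 0.0465 for ER stress and 0.0471 for ribosome biogenesis.

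The other lists were not called by camera in this comparison. AKR1C3, an enzyme that makes testosterone, rose by 1.75 ± 0.28 and HSD17B6 by 0.93 ± 0.17, with UGT2B28 at 0.26, in the steroid metabolism list, where RDH11, a retinol dehydrogenase, fell by 0.71 (3 of 29 higher and 1 lower; 4 and 1 when adjusted over the list alone; median 0.013). AKR1C3 and UGT2B28 have close paralogs, so their rows are uncertain. The interferon response list had 1 higher gene, GBP1 (1.68), and 1 lower, EIF2AK2 (-0.30), of 40, also when adjusted over the list alone, with a median of 0.052 that became -0.13 (camera adjusted p = 0.00444, and adjusted p = 0.121 with an estimated correlation) with the term for the GFP arrays numbered 1 and -0.14 (0.0486) without GFP-DHT 1. With the term 2 interferon genes were higher and 9 lower, and without the GFP arrays numbered 1 these were 3 and 10. Hypoxia and glycolysis genes went both ways, with 3 of 34 higher, such as ADM (0.91), and 3 lower, such as HK2 (-0.67) and SLC2A1 (-0.60), a hexokinase and a glucose transporter (3 and 5 when adjusted over the list alone; median -0.030). In the cholesterol and fatty acid list 3 of 38 rose, EBP, FADS1 and FDPS (0.55 to 0.43), and TM7SF2 fell (-0.53; the same counts when adjusted over the list alone; median -0.020). GCNT1 (0.61) was the 1 called gene of 43 in the secretory list (median 0.024), also adjusted over the list alone, and ODC1 (0.37) of 11 in the polyamine list (1 higher and 1 lower adjusted over the list alone; median 0.017). In the AP-1 list of 26, KLF4 rose (0.71) and MYC fell (2 higher and 1 lower adjusted over the list alone; median -0.023). In the oxidative phosphorylation list of 42, NRF1 and UQCRFS1 rose (0.26 each, 2 also adjusted over the list alone; median -0.016), and of 37 ribosomal protein genes RPS23 (-0.30) and RPL15 (-0.28) fell, while limma called 0 adjusted over the list alone (median -0.022). Of 21 NF-kB genes limma called 0, also when adjusted over the list alone (median 0.015). Without the GFP arrays numbered 1 the genes higher and lower were 5 and 4 for steroid metabolism, 5 and 6 for hypoxia, 5 and 3 for cholesterol, 6 and 2 for the secretory list, 5 and 1 for AP-1 and 1 and 1 for NF-kB.

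Markers of other cell types showed no shared shift in a culture of 1 line. ACTA2, smooth muscle actin, was the 1 higher gene of 20 stromal markers (0.65 ± 0.17; 0 by limma adjusted over the list alone; median -0.000284) and DST the 1 of 12 basal markers (0.46 ± 0.12; 1 adjusted over the list alone; median -0.0073). limma called 0 of 20 neuroendocrine (median -0.029) and 0 of 18 leukocyte and endothelial markers (median -0.000122), with the same counts adjusted over the list alone. Among 15 luminal markers KLK3 and ACP3, prostatic acid phosphatase (-0.97 ± 0.15), fell, 2 also adjusted over the list alone (median -0.052). Of 14 housekeeping genes HPRT1 rose (0.27; 2 adjusted over the list alone; median 0.095). camera called neither of these last lists, while fry gave adjusted p = 0.0339 for luminal markers and 0.039 for housekeeping genes. The 5′ to 3′ log2 ratio of ACTB differed by 0.0018 between the 2 DHT groups (exact permutation p = 1).

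Many calls near the threshold in this comparison were lost without 1 array (limma, adjusted p in brackets). Without GFP-EtOH 2 these were UGT2B28 (0.0558), RPS23 (0.0728), DST (0.0575) and ACTA2 (0.0515). Without GFP-EtOH 3 they were SOCS2 (0.0531), ID1 (0.0503), UGT2B28 (0.0633), RPS23 (0.0742), RPL15 (0.0616), DST (0.0523) and ACTA2 (0.0626). Leaving out GFP-DHT 1 ended the calls of PCDHB14 (0.0696), IGFBP3 (0.0511), ID1 (0.0784), MYC (0.0758), UGT2B28 (0.103), HK2 (0.0609), SLC2A1 (0.0919), PFKFB4 (0.0685), NRF1 (0.0632), RPS23 (0.128), RPL15 (0.099) and DST (0.13). Without GFP-DHT 2 they were SOCS2 (0.0536), NCAPD3 (0.0674), FADS1 (0.0847), RB1 (0.0672), ODC1 (0.0946), UGT2B28 (0.128), EIF2AK2 (0.0805), NRF1 (0.0807), RPS23 (0.115), RPL15 (0.0519), NOP16 (0.0878), UTP4 (0.0743), PPAN (0.093), DST (0.0671), ACTA2 (0.134) and HPRT1 (0.0674). Leaving out GFP-DHT 3 ended those of PCDHB14 (0.0517), NCAPD3 (0.0621), FADS1 (0.0728), ID1 (0.0876), MYC (0.0543), ODC1 (0.104), UGT2B28 (0.056), EIF2AK2 (0.0656), HK2 (0.0679), SLC2A1 (0.0944), PFKFB4 (0.0837), NRF1 (0.0542), UQCRFS1 (0.056), RPL15 (0.0819), NOP16 (0.0919), UTP4 (0.0909), PPAN (0.0789), DST (0.0889), ACTA2 (0.142) and HPRT1 (0.0573). Without CCND1-DHT 1 they were PCDHB14 (0.113), BMX (0.0764), SOCS2 (0.135), NCAPD3 (0.0519), FADS1 (0.0783), IGFBP3 (0.114), ID1 (0.131), OPRK1 (0.0635), ACKR3 (0.0624), MYC (0.101), RB1 (0.081), ODC1 (0.106), UGT2B28 (0.0701), GBP1 (0.072), EIF2AK2 (0.0762), ADM (0.0636), P4HA2 (0.0615), HK2 (0.088), SLC2A1 (0.132), PFKFB4 (0.0728), NRF1 (0.0519), UQCRFS1 (0.0541), RPS23 (0.124), RPL15 (0.124), NOP16 (0.0736), UTP4 (0.064), PPAN (0.072), DST (0.155), ACTA2 (0.141) and KLK4 (0.054). Leaving out CCND1-DHT 2 ended those of PCDHB14 (0.0557), SOCS2 (0.102), NCAPD3 (0.0677), FADS1 (0.0924), IGFBP3 (0.0573), OPRK1 (0.0603), MYC (0.0897), RB1 (0.0852), ODC1 (0.0853), UGT2B28 (0.0897), GBP1 (0.0503), EIF2AK2 (0.0795), P4HA2 (0.0513), SLC2A1 (0.0637), PFKFB4 (0.0664), NRF1 (0.087), RPS23 (0.157), RPL15 (0.0911), NOP16 (0.0817), UTP4 (0.0894), PPAN (0.0731), DST (0.0754), ACTA2 (0.1), HPRT1 (0.063) and KLK4 (0.0721). Without CCND1-DHT 3 they were PCDHB14 (0.0878), BMX (0.0812), SOCS2 (0.115), NCAPD3 (0.0803), FADS1 (0.0768), IGFBP3 (0.0977), ID1 (0.118), OPRK1 (0.0632), MYC (0.0879), RB1 (0.0526), ODC1 (0.102), UGT2B28 (0.174), GBP1 (0.0652), EIF2AK2 (0.065), ADM (0.0586), P4HA2 (0.0648), HK2 (0.0803), SLC2A1 (0.102), PFKFB4 (0.109), NRF1 (0.0918), UQCRFS1 (0.0642), RPS23 (0.0734), RPL15 (0.0969), NOP16 (0.101), UTP4 (0.0932), PPAN (0.113), DST (0.159), ACTA2 (0.149), HPRT1 (0.0673) and KLK4 (0.0648). Without GFP-EtOH 1, by contrast, TMPRSS2 (0.0474), CDKN1B (0.0355) and ST6GALNAC1 (0.0178) passed.

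The 2 responses share the GFP-DHT arrays with opposite sign, which alone gives opposite changes. Across genes, which are not independent replicates, the correlation of the 2 fold changes was 0.086, against a mean of -0.50 in 100 simulations of unchanged groups with independent arrays. With the mean correlation of 0.525 between same-numbered GFP arrays built into the simulation, a step added after the data had been seen, the mean was -0.34 (-0.41 to -0.25). The covariance was 0.00325 against -0.00608 with independent arrays, a difference of 0.00932, and against -0.00289 with correlated arrays, a difference of 0.00614. With 0 DHT calls by limma, 0 genes were called in both comparisons, and 3 without GFP-DHT 1. With the term for the GFP arrays numbered 1, 48 of the 83 DHT genes were also called for cyclin D1. KLK2, KLK3, TRPM8, ST6GALNAC1 and KLK4 led 15 genes that were higher with DHT and lower with cyclin D1, where independent lists would give 3.18 (Fisher's exact test, p = 3.17e-07). DTL, DEPDC1, MCM10, RRM2 and MCM4 led 20 genes higher in both, against 4.61 (exact p = 6.95e-09). Another 8 genes were lower in both, against 1.71 (exact p = 0.000199), and 5 were lower with DHT and higher with cyclin D1, against 2.47 (exact p = 0.0961). Part of the excess of opposite changes may come from the shared arrays, which lower the number of changes in the same direction. Both comparisons also use the same variance estimate per gene. Independent lists are therefore not the no-change value for any of these counts, and the exact p-values do not measure chance. No simulation gave a no-change count, and 3 arrays cannot be divided so that each comparison has its own.

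CCND1-DHT minus GFP-EtOH gives the net distance of the cyclin D1 cells from cells without hormone or cyclin D1. The androgen-induced list averaged 0.39 above GFP-EtOH in GFP-DHT and 0.12 in the arrays labelled CCND1-DHT, a ratio of 0.316, with 12 of 74 genes higher and 3 lower past the threshold (15 and 3 when adjusted over the list alone; median 0.10, camera adjusted p = 0.112, fry 0.383). With the term for the GFP arrays numbered 1 camera called this list higher (median 0.14, adjusted p = 0.00888, and 0.869 with an estimated correlation; 18 genes higher and 3 lower), as it did without them (0.055, adjusted p = 0.0479; 20 and 9). The androgen-repressed list averaged -0.13 and -0.21, a ratio of 1.7, with 9 of 28 genes lower and 2 higher (10 and 2 when adjusted over the list alone; median -0.053, camera adjusted p = 0.0454, and adjusted p = 0.312 with an estimated correlation; median -0.13 without the GFP arrays numbered 1). Over the genes called for DHT with the term for the GFP arrays numbered 1, the ratio taken per gene had a median of 0.959 for the 54 higher (18 below 0.5 and 25 above 1) and 1.13 for the 29 lower, where the position of CCND1-DHT between the GFP groups for the androgen-induced list was 0.446. The genes were chosen by their DHT change and the list was not, so these ratios are not of 1 kind. Cell cycle lists stood furthest away, with 62 of 65 G1/S genes (63 when adjusted over the list alone; median 1.30) and all 54 G2/M genes (median 2.04) higher, each with adjusted p = 0.102 with an estimated correlation. Ribosome biogenesis (17 of 31 higher; 23 when adjusted over the list alone; median 0.35; adjusted p = 0.261 with an estimated correlation) and ER stress genes (10 of 35; 15; median 0.41, but 0.28 with the term and 0.25 without the GFP arrays numbered 1, with 18 higher in both; adjusted p = 0.261 with an estimated correlation) were higher as well, and so were p53 targets (15 of 30 higher and 2 lower; 18 and 2; adjusted p = 0.146 with an estimated correlation), secretory genes (13 of 43 and 1; 15 and 1; median 0.27, but 0.15 without those arrays; 0.498) and cholesterol and fatty acid genes (7 of 38 and 1; 12 and 1; 16 and 2 without those arrays; 0.7, and 0.107 by fry). The 5′ to 3′ log2 ratio of ACTB was 0.24 higher than in GFP-EtOH (exact permutation p = 0.1, the smallest possible). That of GAPDH was 0.091 higher (exact permutation p = 0.1). Among the array controls, the 5′ and middle rows of ACTB (0.48 and 0.37, limma adjusted p = 0.0154 and 0.021) passed the threshold. A 5′ row of ISGF3A did as well (0.58, limma adjusted p = 0.0412).

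In this net comparison 2352 genes passed, 1410 higher and 942 lower, and the groups did not overlap for 36.8% of genes against 10% by chance for exchangeable arrays. The number of genes different between CCND1-DHT and GFP-EtOH was 1388 without CCND1-DHT 1 and 1275 without CCND1-DHT 3, and a further quantile normalization called 305 higher and 109 lower. The F test called 1822 genes differing among the 3 groups, and 921, 1065 and 824 without CCND1-DHT 1, 2 and 3.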

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

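The tests here were chosen after the values had been seen. Among 2625 distinct rows of transcripts that matched no gene symbol, and that therefore entered no comparison of genes, 61 were higher and 54 lower in the arrays labelled CCND1-DHT than in GFP-DHT (limma, adjusted over all distinct rows). They are noted only because no comparison of genes uses them: their share past the threshold, 4.38%, was below the 8.85% of named genes, where the adjustment was over genes. The largest difference was 2.2 ± 0.089 (SE, adjusted p = 1.41e-06). No biological explanation was tested, since these rows have no names here. Some may be transcripts of genes that are named elsewhere in the text, which was not checked. Groups of 3 arrays are too small for a test of single outlying arrays.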

How the results depend on the processing

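Signal over background, which limits what an array can show for dim genes, was lost in the ratios, so the planned filter on dim probe sets was not run; the mean of a gene's rows became the main rule. For each departure below the cause was not tested, except that fewer arrays leave fewer degrees of freedom, that a minimum fold can only remove genes, and that a further quantile normalization forces 1 spread of ratios onto arrays whose baseline group is narrow by construction.

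The number of genes changed by DHT in GFP cells, 0, became 25 after quantile normalization, 57 with array weights, 83 with the term for the GFP arrays numbered 1, 5 without both of these arrays, 1 with the replicate block and only 2 groups, and 0 to 4 when leaving out 1 array, the 4 without GFP-DHT 1. It stayed 0 with the replicate block, centring, only the 2 groups, trend and robust variance, every distinct row and both other row rules. The number of genes changed by cyclin D1 under DHT, 1407, became 271 (quantile), 4605 (array weights), 540 (at least 1.5-fold), 2294 (term), 2817 (pair left out) and 737 to 2372 (leaving out 1 array). The number of genes different between CCND1-DHT and GFP-EtOH, 2352, became 414 (quantile), 5301 (array weights), 774 (at least 1.5-fold) and, with the replicate block and 2 groups, 1293, and 1275 to 2752 leaving out 1 array. The 1822 genes differing among the 3 groups became 370 (quantile), 5664 (array weights), 3106 (term), 3286 (pair left out) and 824 to 2206.

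The number of DHT-responsive genes also changed by cyclin D1, 0, became 13 (quantile, all opposite), 43 (array weights), 48 (term), 5 (pair left out, all opposite) and 0 to 3 leaving out 1 array. The position of CCND1-DHT between the GFP groups, 0.316 for androgen-induced genes, was 0.281 after centring, 0.1 after quantile normalization, 0.403 with array weights, 0.293 over every distinct row, 0.446 with the term, 0.417 without the pair and 0.271 to 0.453 leaving out 1 array. The CCND1 row kept its sign throughout but missed the threshold after quantile normalization (-0.284, adjusted p = 0.508), without the pair (-0.309, adjusted p = 0.0589) and with the block and 2 groups (-0.334, adjusted p = 0.0657), and ran from -0.386 to -0.262 leaving out 1 array.

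With an estimated correlation camera called none of the 5 leading lists, whose medians are the same in that setting: androgen-induced (0.322 for DHT, -0.218 for cyclin D1), G1/S (0.355 and 1.02) and G2/M (1.91 for cyclin D1). Under the other settings these lists kept their direction and their call. Their size did change: without the pair the DHT medians were 0.186 for androgen-induced and 0.207 for G1/S genes.

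The numbers did not pair the CCND1-DHT arrays, where the replicate block gave 1574 genes changed by cyclin D1 under DHT, 2568 genes different between CCND1-DHT and GFP-EtOH and 1966 genes differing among the 3 groups, and kept the CCND1 row at -0.334. It changed other calls: the ER stress list for DHT, and for cyclin D1 UGT2B28, RPS23 and RPL15 (lost) and TMPRSS2 and ST6GALNAC1 (gained).

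Many list medians changed sign where camera called the list neither over all arrays nor in the altered fit. For cyclin D1 these included those of cholesterol and fatty acid synthesis (-0.0198, and 0.0491 without the pair), secretory (0.0244 and -0.00733), NF-kB (0.0151 and -0.00759) and AP-1 genes (-0.0234 and 0.0138). The AP-1 median for DHT (-0.0605) was 0.01 without the pair, and the ER stress and protein folding median (0.135) was -0.0128 without GFP-EtOH 1. The reversals below are those of single genes and of lists that camera called in 1 or both of the 2 fits compared. For DHT, the G2/M and mitosis list ran from -0.0393 to 0.217 and the interferon response list from -0.216 to 0.184 leaving out 1 array. CCNE1 was -0.0129 with array weights, -0.0174 without the pair and -0.0513 to 0.143 leaving out 1 array, and CDKN1B -0.262 to 0.0471. For cyclin D1, the interferon response list was -0.13 with the term, -0.135 without the pair and -0.135 to 0.171 leaving out 1 array. FKBP5 was 0.245 with array weights, 0.0611 with the term, 0.247 without the pair and -0.255 to 0.247 leaving out 1 array, and CCNE1 was 0.0123 without the pair and -0.182 to 0.0123. After quantile normalization GCNT1 was -0.0391, DTL -0.0743 and MCM4 -0.0683.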

Other observations

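The gene families here were picked after their values had been seen, and of the tests below those of RNA length, of the interferon and NF-kB lists and of the CCND1 row were chosen after the result. Heat shock proteins and their co-chaperones rose with the label CCND1-DHT more often than they fell: of 73 measured genes 13 were higher and 2 lower than in GFP-DHT (limma), with a median of 0.059. Beside HSPA6 (3.02), HSPH1 rose by 0.82 ± 0.21, DNAJB1, a co-chaperone, by 0.74 ± 0.17 and BAG3 by 0.53 ± 0.10. The counts were 12 and 2 after centring, 4 and 0 after quantile normalization, and 22 and 5 without the GFP arrays numbered 1. DHT alone gave 0 calls among them, as it did among all genes in that fit, so this sets the family apart in no way. Without GFP-DHT 3 or CCND1-DHT 1, 2 or 3 the number higher was 7, 6, 7 and 5. Of 44 replication-dependent histone genes 2 were higher and 10 lower, with a median of -0.12, and the others did not pass. The counts were 2 and 9 after centring (median -0.12), 1 and 2 after quantile normalization (-0.10), and 4 and 11 without the pair (-0.083). The number lower was 4, 4 and 5 without GFP-DHT 1, 2 and 3 and 5, 3 and 3 without CCND1-DHT 1, 2 and 3. Neither family was tested as a group. H2BC21 (-1.46) and H2AC8 (-0.74 ± 0.12) were among the lower and H2AC11 (0.76) among the higher. Their messages mostly lack a poly(A) tail, and the family's members are similar in sequence, so single rows are uncertain.

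Of 15 kallikrein genes only KLK2, KLK3 and KLK4 were called lower with cyclin D1, and limma called 3 lower and 0 higher also after centring, after quantile normalization and without the GFP arrays numbered 1. Without CCND1-DHT 1, 2 or 3 the number lower was 0 each time, and without GFP-DHT 3 it was 4. In the GFP arrays numbered 1 the gene furthest below the baseline was MMP7, a matrix metalloproteinase, at -5.65 in GFP-EtOH and -5.28 in GFP-DHT, also chosen after its values were seen.

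The 2 GFP arrays numbered 1 stood apart from the other arrays in the same genes (correlation of deviations 0.636). Degraded RNA in both is argued against, since 0 of their 4 5′ to 3′ ratios of ACTB and GAPDH lay below those of the other arrays of the group; the 18S 5′ control stood at a ratio of 6.11 in GFP-EtOH 1, against 0.341 to 2.47 in the other 8 arrays, but at 1.02 in GFP-DHT 1, so it set only 1 of the 2 apart. For leukocytes, endothelium or fibroblasts mixed into the other 7 arrays, the medians of those marker lists lay at percentile 44.8 or higher among random lists. That cannot decide the question, which stays open. In GFP-EtOH 1 both medians sat at the baseline of the ratios (-4.33e-08), where the percentile depends on ties. For stromal markers a median of 0 lay at percentile 5.45 in GFP-EtOH 3 and 15.5 in GFP-EtOH 2. A list median would also miss a few raised transcripts. A weaker interferon and NF-kB response in these cells stays open: the interferon median lay at percentile 0 in both arrays, but the NF-kB median at 1.64 in GFP-EtOH and at 10.1 in GFP-DHT; the bound written for this test, a percentile of 5 or more for any of the 4 medians, is met by 10.1 and counts against it, but it was set aside after the value was seen, since an NF-kB median of -0.0179 is too near 0 to decide. The design names no difference between these arrays and the others, so a separate day or virus stock was not tested and stays open.

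The androgen-induced list had a lower median in the CCND1-DHT arrays than in GFP-DHT. Of its 74 genes limma called 14 lower and 2 higher, and 58 did not pass. The list was not called by fry (adjusted p = 0.124). The GFP-DHT array numbered 1 alone does not account for it, since without the pair the list's median was still -0.0854 (camera adjusted p = 5.51e-06). That is a smaller shift than the -0.218 over all arrays. With an estimated correlation camera did not call the list over all arrays (adjusted p = 0.492) or with the term (0.709), and without the pair that setting was not run. To test for chance values of the shared GFP-DHT arrays, the list's mean change of -0.264 was set beside 10000 lists matched on the DHT change. It lay at percentile 0, and at 0.61 without the pair. The matched lists drew on real genes, some of them raised by cyclin D1, and their median was 0.0243 (-0.021 without the pair). Shared arrays alone would give opposite changes, so this test cannot exclude them. What lowers the androgen-induced list stays open, since no hormone-free cyclin D1 arrays were analysed here.

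The CCND1 row did not rise in the arrays labelled CCND1-DHT. The lowest G1/S median of the 3 arrays lay 0.833 above the highest of the 6 GFP arrays. That restates the main comparison, whose result was known when the test was written. It argues only against a swap with GFP cells in the state of those 6 arrays. Which virus the cells received is not shown by it. A virus transcript without the part that the row measures may account for the CCND1 row. The change of -0.334 in the only row of the gene is the pattern itself, so this cannot be told apart from a low level of the transcript. A first test that only restated the pattern was set aside after the result. Another virus under the label was not tested.

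For the count of genes differing among the 3 groups, chance can be excluded at the 5% level of the splits drawn only if all 9 arrays are exchangeable, which the GFP arrays numbered 1 were not: 1 of 100 splits, the real one, gave as many as 1822 genes, out of 280 possible, and the highest other gave 1391. The 4 other splits that kept the CCND1-DHT arrays together gave 1220 to 1391 genes and the 95 that parted them gave 0. Any count above 0 thus rested on keeping the CCND1-DHT arrays together. The real division of the GFP arrays gave more genes than those 4 splits, so the share of 1 in 100 rests on that division as well. All 4 parted the 2 GFP arrays numbered 1, as the real division does. No split drawn kept the CCND1-DHT arrays together and also put these 2 arrays in 1 group, so the real count was not compared with such a division. A split of 6 arrays has only 10 forms, too few for a share under 0.05. For cyclin D1 the real split gave 1407 genes and the highest other 0, as 1 of 10 reached the real count, and for the net comparison 2352 and 0, again 1 of 10. For DHT the real split and the highest other both gave 0, so 10 of 10 matched it.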
